A study of Arabidopsis thaliana with 12 samples.

How the data were processed

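RNA was measured by sequencing in 12 libraries of 14-day-old Arabidopsis thaliana seedlings, 3 biological replicates each of the wild type (WT), the single mutants val1 and val2 and the val1 val2 double mutant, per the series' design text. VAL1 (AT2G30470, also called HSI2) and VAL2 (AT4G32010, also called HSL1) encode transcriptional repressors with a plant B3 DNA-binding domain. Per the labels' protocols, seeds were kept 3 days at 4 °C in the dark, seedlings grew on plates with 1% sucrose and 0.6% agar under 16 h of light and 8 h of dark at 22 °C, and total RNA was taken from about 100 mg of seedlings with a kit. Groups and replicate numbers came from the sample titles, with which the file names of val1 replicates 2 and 3 disagree; both files are named for val1. The series also lists genome binding data, which were not analysed here.

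The deposited values were FPKM (fragments scaled to transcript length and library total), which the authors computed with Cufflinks per library, per the file headers, with 1 line per assembled locus giving its position, its FPKM, the bounds of a confidence interval and a status. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff, MACS2 and the genome build TAIR10 without saying what each was used for. The files held no gene names and no locus at an FPKM of 0, and each library had its own loci, so a transcript with no assembled locus in a library is listed at 0 here. FPKM are relative to the sequenced total of each library, so a few very abundant transcripts lower all others, and the FPKM of a locus near the fragment length can be inflated.

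Loci were assigned to genes by position against the table of 27432 protein-coding genes on chromosomes 1 to 5 of the assembly TAIR10.1. That build differs in name from that of the files, so the 2 were compared first: over 3 equal parts of each chromosome the median locus began 64 to 76 bases inside the annotated start and ended 70 to 79 bases inside the annotated end. A gene's value was the sum over its loci of the FPKM times the share of the gene that the locus covered. A gene was left missing in a library where its locus covered at least 50% of several genes and the gene itself did not make up 75% of it (3900 genes in any library), where loci were shared with a neighbour (1230 genes), and where no locus was listed while both other replicates reached 10 FPKM (147 values of 132 genes), since such gaps occur when an assembly fails. Over 16010 genes, the mean within-group SD was 0.281 on the log2 scale by this rule, against 0.301 for the largest locus as listed. Genes of near-identical families, such as the RBCS and LHCB genes, and genes overlapping on opposite strands remain uncertain, because the assembly could share fragments between them.

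Libraries held 19164 to 20293 loci with FPKM summing to 907453 to 1113777. The files give no read counts, and the FPKM could not be turned back into whole reads. The widths of the confidence intervals imply about 9.38 to 12.1 M fragments (M, 1e6) per library and a median of 209 to 322 fragments per locus, an approximate figure that is too low for some of the most abundant short transcripts.

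Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in 1 fit of 4 group means over all 12 libraries with a mean-dependent prior, so that a fold change is on the FPKM + 1 scale and understates the change of low genes. The fit held 17654 genes with an FPKM of at least 1 in at least 3 libraries and at least 2 values in each group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the part of the calls with a log2 change of at least 1 is given beside it. The contrasts were each mutant against WT, the double mutant against each single mutant, and the interaction (the change in the double mutant minus the sum of the changes in the single mutants). Tested on simulated data for val1 against WT over 17654 genes, this fit recovered 62 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, with 5 false calls. The changed genes all had a WT mean above 5 FPKM on the log2(FPKM + 1) scale, so recovery of lower genes was not tested. P-values are two-sided. Assignment and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

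Groups, tests, gene lists and alternatives were fixed before the data were examined. The 16 lists, 274 genes in all, were seed maturation regulators, seed storage proteins, oil bodies and seed oil, late embryogenesis and desiccation, floral MADS and floral identity, flowering time, meristem and KNOX, Polycomb and VAL partners, photosynthesis, auxin synthesis and transport, abscisic acid metabolism and response, gibberellin metabolism, root tissue markers, cell division, stress and defence, and reference genes. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 16 lists of a comparison, and again with a correlation estimated per list (statmod 1.5.0). The genes named are, for each comparison with WT, the 10 called genes with the largest rise and the 10 with the largest fall whose mutant libraries lay all above or all below the WT libraries, 5 each way for the interaction, up to 4 members of each list with the smallest adjusted p, and 13 genes named whatever their values (VAL1, VAL2, VAL3, LEC1, LEC2, FUS3, ABI3, AGL15, FLC, AG, SEP3, DOG1 and FT). In 3 lists added after the data were seen (circadian clock, rapid touch and wound response, iron deficiency response), the genes named are among the 4 with the smallest adjusted p in the comparison described. That rule was applied to these lists after their values were seen, and it put MYB44 in the place of ZAT10 and BHLH101 in the place of BHLH38. Other genes named were chosen after their values were seen and are said to be so.

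Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-ratio, TPM and quantile scaling, the replicate number as a block, only the compared groups in the fit, robust prior variances, weights per library, each library left out in turn, and an estimated correlation or a rotation test (fry) for lists. Other rules for assigning loci to genes, for missing loci and for loci under 300 bases were added after the data were seen.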

Results

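The series profiled RNA from whole 14-day-old Arabidopsis seedlings of 4 genotypes, WT, val1, val2 and val1 val2, with 3 libraries each. Each library listed 19164 to 20293 assembled loci with their FPKM. The comparisons ask which genes differ when the repressor VAL1 or VAL2 is mutated, and which changes appear only when both are mutated. As whole seedlings were used, altered tissue makeup and altered expression within cells cannot be told apart.

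The mutated genes themselves were examined first. VAL2 stood at 20.5 ± 2.45 FPKM in WT (SD, n = 3), at 10.5 ± 0.792 in val2 and at 12.8 ± 0.307 in val1 val2. Its log2 change of -0.90 in val2 (SE 0.133, limma adjusted p = 0.00446) and -0.63 in val1 val2 (adjusted p = 0.00207) passed the threshold. VAL1 stood at 16.5 ± 1.78 FPKM in WT, 7.66 ± 4.38 in val1 and 15.6 ± 6.11 in val1 val2, and neither change passed (adjusted p = 0.0835 and 0.744). The VAL1 change in val1 passed without val1 replicate 1 (adjusted p = 0.0111) or without val1 val2 replicate 3 (0.042). VAL2 was also lower in val1, at 13.6 ± 2.21 FPKM (adjusted p = 0.0423), a call that was lost on leaving out any of 9 of the 12 libraries (adjusted p 0.0541 to 0.152). VAL3, a related gene, stood at 2.34 ± 1.02 FPKM in WT and 0.377 ± 0.653 in val1 val2 (adjusted p = 0.00887).

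The assembled loci showed more than the levels. On chromosome 2 (TAIR10), the WT libraries each had 1 locus over VAL1, ending at 12985142 to 12985228. In val1 replicates 2 and 3 this was broken in 2, with 0.504 and 0.949 FPKM in the part before position 12982815 and 10 and 9.6 FPKM in the part from there on. In val1 val2 replicates 1 and 2 only the part from 12982815 on was assembled, at 26.6 and 22.3 FPKM. By contrast val1 replicate 1 and val1 val2 replicate 3 had a single locus over the gene at 13.7 and 24.3 FPKM. Over VAL2 on chromosome 4, a shorter locus was listed in val2 replicates 2 and 3 and val1 val2 replicate 1, ending at 15483528, 15483308 and 15483301. In val2 replicate 2 a second locus at 0.716 FPKM followed, from 15483699 to 15485116. The other 3 libraries labelled val2 or val1 val2 had unbroken loci, val2 replicate 1 at 9.98 FPKM and val1 val2 replicates 2 and 3 at 14 and 13 FPKM, ending at 15485351, 15485127 and 15485273. The loci of WT ended at 15485150 to 15485353. The names of the deposited files disagree with the sample titles for val1 replicates 2 and 3, and the titles were followed, so which of these 2 libraries is which is uncertain. The labels give no positions for the lesions. The unbroken loci of val1 replicate 1 and val1 val2 replicate 3 cross position 12982815, where the loci of the other 4 libraries labelled val1 or val1 val2 are broken or begin, and so go against these labels if the lesion lies there. The unbroken VAL2 loci of val2 replicate 1 and val1 val2 replicates 2 and 3 go against theirs in the same way if the VAL2 lesion lies beyond 15483301. Across genes, val1 replicate 1 correlated with WT at 0.959 to 0.965 (Pearson), below the 0.979 to 0.982 among val1 libraries. For val2 replicate 1 this was 0.953 to 0.962, below the 0.980 to 0.982 among val2 libraries. These values argue against a WT library under these 2 labels, while a mixture of plants was not tested by them. Groups are named by their labels throughout. The VAL2 decrease was no longer called when the FPKM of the largest locus was used as listed (adjusted p = 0.214 in val2 and 0.122 in val1 val2), because the main value multiplies FPKM by the share of the gene covered.

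**Figure D1:**
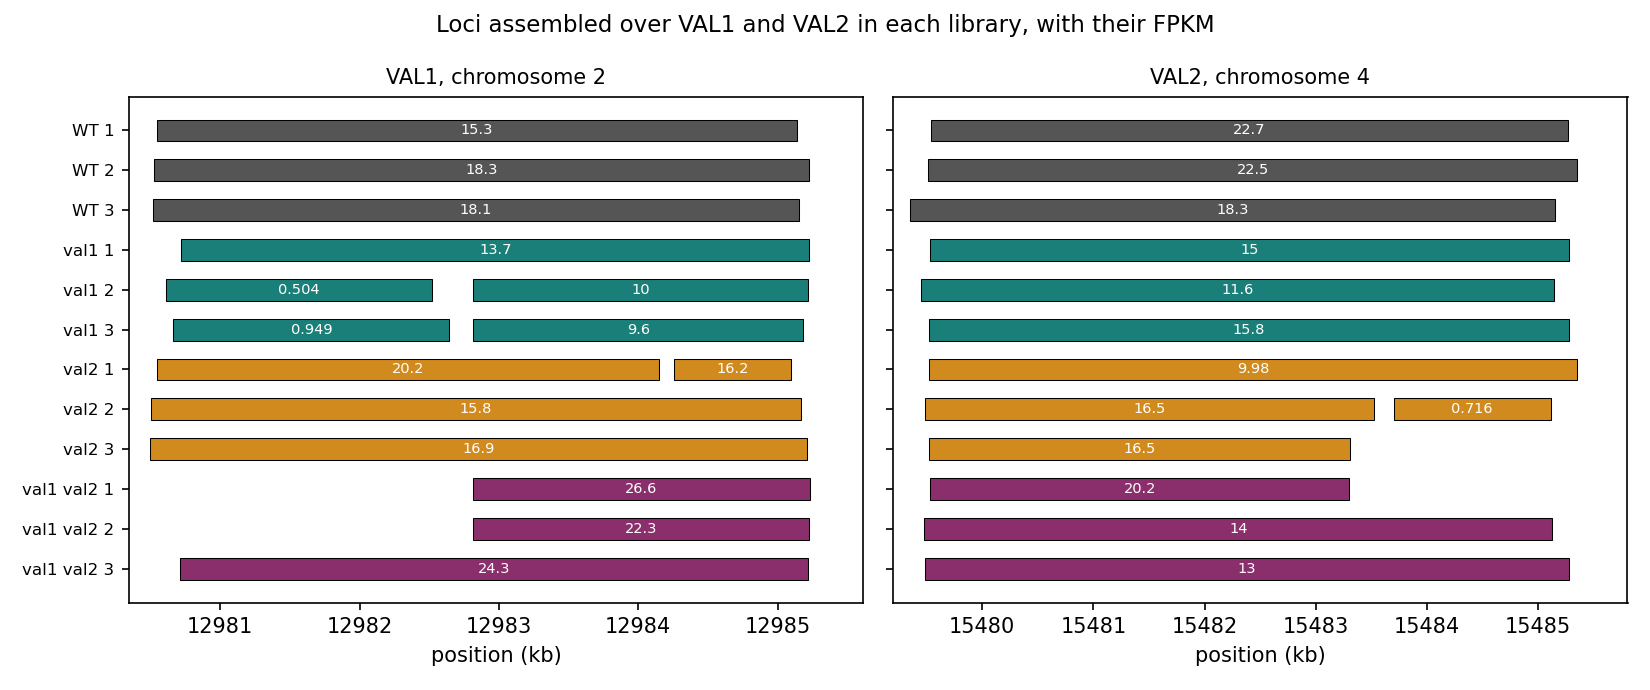
Loci assembled over VAL1 (left) and VAL2 (right) in each library, drawn by their position in kb as the files give it, with the FPKM of each locus printed on it. In val1 replicates 2 and 3 and val1 val2 replicates 1 and 2 a locus begins at 12982815 within VAL1.

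Genome-wide, the double mutant stood apart. The first principal component held 76.1% of the variance of 16024 genes with complete values. It placed the 3 val1 val2 libraries at scores of 155, 142 and 107 against -52.1 to -34.8 for the other 9 libraries. Replicates of WT correlated at 0.976 to 0.979 (Pearson, across genes, which are not independent replicates), those of val1 at 0.979 to 0.982 and those of val2 at 0.980 to 0.982, but those of val1 val2 at 0.927 to 0.970. The double mutant libraries were also uneven in their distance from WT: replicate 3 correlated with the WT libraries at 0.769 to 0.782, replicate 2 at 0.687 to 0.697 and replicate 1 at 0.645 to 0.656. The median SD of a gene within a group was 0.266 on the log2 scale in val1 val2 and 0.124 to 0.142 in the other groups. The 10 most abundant loci took 14.8, 14.8 and 10.9% of the FPKM in the double mutant libraries and 5.51 to 7.75% in the other 9.

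In val1 seedlings, seed reserve genes that had no locus in any WT library were listed at low levels. For most of them carry-over from the val1 val2 libraries was not excluded, as described further below. The 2S albumin genes SESA2, SESA3 and SESA4 reached 20 ± 1.96, 24.2 ± 0.921 and 19.9 ± 2.77 FPKM (SD, n = 3; limma adjusted p = 9.37e-07, 3.46e-06 and 2.29e-07). The vicilin-like gene PAP85 reached 25.5 ± 2.62 (1.09e-05). The 12S globulin genes CRA1 and AT4G28520 stood at 8.82 ± 0.203 and 10.8 ± 0.899 FPKM (6.83e-07 and 1.09e-06). Of 12 measured storage protein genes 10 were called higher over all genes and 10 when adjusted over the list alone (camera adjusted p = 5.01e-106). Against their levels in val1 val2 these are small, with a median of 0.113% over the storage genes that had a locus in every val1 library. Oil body genes followed: OLEO1, an oleosin that coats oil bodies, stood at 9.33 ± 0.524 and the steroleosin HSD5 at 5.17 ± 0.677 FPKM, both listed at 0 in WT. OLEO3 rose from 0.84 ± 0.829 to 12.5 ± 0.871. Of 12 oil genes 4 were called higher, as many as when adjusted over the list alone (camera adjusted p = 5.23e-14). Of 20 late embryogenesis genes 6 were, again as many over the list alone (3.44e-10), among them the seed tonoplast aquaporin TIP3;2 at 9.11 ± 2.14, the dehydrin XERO1 at 2.76 ± 0.468 and LEA18 at 4.02 ± 2.02 FPKM. These 3 list calls held with an estimated correlation. The call of SESA2, SESA3 and SESA4 was lost when the missing loci of those genes in val1 val2 replicate 1 were entered as 0 (adjusted p 0.482 to 0.49), which widens the spread shared by all groups.

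Single genes of the flowering and Polycomb lists changed in val1. FLC, the MADS-box repressor of flowering, rose from 4.31 ± 0.246 to 28.3 ± 9.9 FPKM (log2 change 2.41, SE 0.191, limma adjusted p = 4.11e-05). Its relative MAF5 rose from 10.2 ± 0.476 to 35.4 ± 2.69 (log2 change 1.70, adjusted p = 1.07e-05). AGL15, a MADS-box gene of embryos, rose from 3.06 ± 0.262 to 16.8 ± 2.02 (log2 change 2.13, SE 0.184, adjusted p = 7.45e-05). LEC1, LEC2, FUS3 and ABI3, the central activators of seed maturation, had no locus in any val1 library. BMI1A and BMI1B, RING finger proteins of the Polycomb repressive complex PRC1, rose from 6.67 ± 0.165 to 19.9 ± 2.14 (adjusted p = 6.35e-05) and from 6.69 ± 0.421 to 16.0 ± 1.24 FPKM (0.000745). They were the 2 of 20 Polycomb and partner genes called (as many over the list alone), and that list did not pass (camera adjusted p = 0.0549, and 0.0149 to 0.24 over 30 alternatives, of which 11 passed). SEP4, a floral MADS-box gene, fell from 7.29 ± 0.32 to 2.28 ± 0.282 (0.000136). Of 21 flowering time genes 4 were higher and 1 lower (5 and 1 when adjusted over the list alone). The list passed camera as higher (adjusted p = 0.0158), with a mean log2 change of 0.131 and a median of -0.005, and was lost with an estimated correlation (adjusted p = 0.181) and without WT replicate 1 (0.0601) or 3 (0.0884). The calls of MAF4 (5.70 ± 0.6 to 14.0 ± 2.49) and TEM1 (36.0 ± 3.37 to 66.2 ± 5.25) within it were lost without WT replicate 1 (adjusted p = 0.0623 and 0.0525), and that of MAF4 also without val1 replicate 1 (0.0552).

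Single-gene extremes in val1 lay mostly outside the lists. AT1G03106 stood at 74.0 ± 5.29 FPKM against none in WT and AT1G02770 rose from 0.401 ± 0.367 to 57.5 ± 4.27 (log2 change 5.42, SE 0.285). Among the 10 largest rises were also AT1G47540 at 25.2 ± 1.41 and AT3G02677 at 20 ± 3.33, both listed at 0 in WT. AT2G20270 and AT1G75945 stood at 72.2 ± 2.82 (n = 2) and 43.2 ± 2.74 FPKM in val1 and at 73.7 ± 2.62 (n = 2) and 41.3 ± 4.5 in val2, against no locus in WT. The call of AT2G20270 was lost when missing loci were entered as 0 (adjusted p = 0.181 in val1). The largest falls included AT1G47400, AT1G47395 and AT2G30766, which encode the iron deficiency peptides of the IRON MAN family, from 19.7 ± 7.79, 36.7 ± 16.7 and 21.1 ± 6.84 FPKM to 0, 1.03 ± 0.981 and 0.392 ± 0.679 (limma adjusted p = 6.35e-05, 0.000234 and 0.000122). The call of AT2G30766 was lost with the FPKM of the largest locus (0.0548). ARR7, a cytokinin-induced response regulator, fell from 44.3 ± 9.42 to 5.29 ± 0.812 (log2 change -2.83, adjusted p = 0.000489). AT1G13609, AT3G29633, AT4G23840 and AT3G59390 went from 47.6 (n = 2), 13.6, 6.04 and 5.82 FPKM to no locus. Weaker calls were AT2G47880 (18.8 ± 1.71 to 2.44 ± 2.42), lost without WT replicate 1 (0.0541), and AT2G03430 (26.8 ± 2.29 to 5.04 ± 4.84), lost without any of 9 libraries (up to 0.138).

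In all, 686 of 17654 genes were called in val1 against WT, 385 higher and 301 lower, 345 of them by at least 2-fold. In 5662 genes (32.1%) the 3 val1 values lay all above or all below those of WT, where chance gives 10%. Leaving out WT replicate 1, WT replicate 2, val1 replicate 2 or val1 replicate 3 gave 389, 414, 437 and 423 calls, and leaving out the uneven val1 val2 replicate 3, which enters only the shared spread, gave 1280. Weights per library gave 1877. Of the other lists, photosynthesis had 2 called members (3 over the list alone), LHCB2.2 and LHCB2.1, light-harvesting proteins at 45.7 ± 4.17 and 29.4 ± 2.65 FPKM against 20 ± 1.11 and 17.56 ± 1.65 in WT, lost without any of 6 and 5 libraries (adjusted p up to 0.0827 and 0.0929). The drought-induced gene RD29A fell from 52.1 ± 20.2 to 8.29 ± 1.58 FPKM (adjusted p = 0.00128). CHS, the first enzyme of flavonoid synthesis, fell from 63.3 ± 13.8 to 18.1 ± 3.28 (0.00459) and GA3OX1, which makes active gibberellin, from 4.72 ± 1.48 to 1.76 ± 0.329 (0.00638). The 12 lists not called had camera adjusted p of 0.0549 to 0.896, with Polycomb and VAL partners at 0.0549 and seed maturation regulators at 0.0559. The median and the mean differed in sign for abscisic acid (0.048 and -0.337) and cell division (0.055 and -0.072).

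In val2 seedlings the largest changes were of single genes, in both directions, and the stress and defence list did not pass, with 1 of 11 genes higher and 1 lower (as many over the list alone; camera adjusted p = 0.778). COR15A, a cold-induced chloroplast protein, rose from 0.851 ± 0.751 to 56.9 ± 26.9 FPKM (SD, n = 3; log2 change 4.94, SE 0.495, limma adjusted p = 0.000421). VSP2, a jasmonate-induced vegetative storage protein, rose from 4.21 ± 1.25 to 55.7 ± 1.99 (3.47, SE 0.227, 4.59e-05). MBP1, a myrosinase-binding protein, rose from 1.81 ± 0.421 to 33.7 ± 11.2 (3.58, 9.13e-05) and AT3G28220 from 1.90 ± 0.185 to 56.9 ± 15 (4.29, 4.59e-05). WRKY18, a transcription factor of defence, fell from 43.5 ± 6.36 to 4.87 ± 0.935 (log2 change -2.92, SE 0.417, 0.00352). AT2G24600 fell from 25.1 ± 10.6 to 0.864 ± 0.139 (-3.72, 0.00038), and AT5G19240 from 43.3 ± 16.3 to 2.64 ± 0.727 (-3.54, 0.00191). AT3G29633 and AT5G36925 stood at 13.6 ± 6.56 and 7.11 ± 2.9 FPKM in WT and had no locus in val2, and AT3G03341 stood at 10.6 ± 2.88 in val2 only among these 2 groups. Calls among the largest that were lost on leaving out 1 library were PP2-A5 and AT5G19130 (any of 6 libraries, adjusted p up to 0.115 and 0.0783), AT5G20790 (4 libraries, up to 0.0696) and CRK41 (3 libraries, up to 0.0745). The log2 changes of PP2-A5 and AT5G19130 stayed at -3.39 to -2.98 and -3.62 to -3.51 when single libraries were left out. ORC4 stood at 15.6 ± 15.5 FPKM, AT2G31820 and AT5G16680 had n = 2, and AT1G21610 went from 13.5 ± 0.886 (n = 2) to no locus. AT5G16680, AT1G21610 and AT2G20270 were no longer called with missing loci entered as 0 (0.144, 0.108 and 0.0703).

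Seed storage genes were listed at trace levels in val2 as well, where carry-over from the val1 val2 libraries was not excluded either. SESA4, SESA2, SESA3 and CRA1 stood at 3.05 ± 0.563, 2.80 ± 0.704, 3.74 ± 0.379 and 1.49 ± 0.246 FPKM against no locus in WT (limma adjusted p = 9.77e-05 to 0.000961), with a median of 0.0182% of the val1 val2 level over the storage genes that had a locus in every val2 library. Of 12 storage genes 5 were called higher (6 when adjusted over the list alone, camera adjusted p = 2.36e-12). The list held with an estimated correlation and was lost with fry (adjusted p = 0.0928), and SESA4, SESA2 and SESA3 were no longer called with missing loci entered as 0 (0.799, 0.812 and 0.781). Gibberellin metabolism was lower as a list (camera adjusted p = 0.011, 0.0124 with an estimated correlation), with 1 of 9 genes higher and 3 lower (1 and 4 over the list alone). It was lost with only WT and val2 in the fit (adjusted p = 0.1), with quantile normalization (0.0825) and with the filter of 5 FPKM (0.233). GA2OX8, which inactivates gibberellin, went from 2.67 ± 0.519 FPKM to no locus (0.000269). GA3OX2, which makes it, stood at 0.186 ± 0.322 in WT and 1.62 ± 0.267 in val2 (0.0291, lost without any of 5 libraries, up to 0.121). Root tissue markers were lower (camera adjusted p = 0.0269, but adjusted p = 0.815 with an estimated correlation), with 3 of 14 genes called (as many over the list alone). The list was lost without WT replicate 3, val2 replicate 1 or val1 val2 replicate 1 or 3 (adjusted p 0.0656 to 0.108). Among them was the root hair cell wall gene PRP3, which fell from 38.6 ± 2.38 to 17.1 ± 3.25 FPKM (0.00538). Cell division genes passed camera as higher (0.0269, but adjusted p = 0.367 with an estimated correlation and 0.0928 with fry), with 0 of 14 called by limma over all genes or the list alone and 6 higher at an unadjusted p under 0.05. The list was lost without WT replicate 2, val2 replicate 2 or val1 val2 replicate 3 (0.0696, 0.147 and 0.0743). FLC stood at 4.27 ± 0.272 and AGL15 at 3.37 ± 0.512 FPKM, close to WT (log2 changes -0.01 and 0.10, adjusted p = 1 and 0.856). FT, the mobile activator of flowering, fell from 3.18 ± 1.53 to 0.428 ± 0.742 (0.0254), a call lost without WT replicate 1 or 2 or val2 replicate 1 or 2 (adjusted p 0.087 to 0.11). RD29A fell to 10.2 ± 3.01 FPKM (0.0034) and the heat shock chaperone HSP101 from 8.45 ± 1.08 to 3.52 ± 0.443 (0.00379).

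In total 780 genes were called in val2 against WT, 310 higher and 470 lower, 371 of them by at least 2-fold, and in 5917 genes (33.5%, chance 10%) the 3 values of each group did not overlap. The count moved when 1 library was left out: it was 419 and 332 without WT replicate 1 and 2, 310, 480 and 421 without val2 replicate 1, 2 and 3, and 1619 without val1 val2 replicate 3. With only WT and val2 in the fit it was 1297, and with weights per library 2310. TPM scaling gave 863 calls with 233 higher (27%), against 39.7% higher as deposited. The 12 lists not called had camera adjusted p of 0.188 to 0.919. Median, mean and test differed in sign for abscisic acid (median -0.022, mean 0.162), stress and defence (mean 0.043, tested as lower at 0.778) and reference genes (0.096 and -0.02).

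In val1 val2 seedlings the seed program was expressed at high levels. FUS3, ABI3 and LEC1, the B3 and NF-Y activators of seed maturation, stood at 78.8 ± 11.6, 38.5 ± 8.1 and 16.0 ± 2.41 FPKM (SD, n = 3; limma adjusted p = 3.5e-11, 6.15e-10 and 1.09e-09). The seed bZIP factor BZIP67 stood at 35.7 ± 6.99 (5.06e-10). All 4 had no locus in any of the 9 other libraries. AGL15 rose from 3.06 ± 0.262 to 76.7 ± 19.7 FPKM (log2 change 4.23, SE 0.184, 1.75e-08). DOG1, which sets seed dormancy, stood at 97.9 ± 44.8 against 0 in WT (9.04e-08), and LEC2 at 1.67 ± 0.819, too low to be tested. Storage proteins were among the most abundant transcripts. The globulins AT4G28520, CRA1 and AT1G03880 stood at 9102 ± 1997, 8190 ± 1696 and 2169 ± 601 FPKM. The albumins SESA3, SESA4, SESA2 and SESA1 stood at 24650, 14900, 14200 and 10550 in the 2 libraries where they had a locus (none in replicate 1), and SESA5 at 5063 ± 1963. OLEO1 and OLEO2 stood at 11410 ± 4095 and 5338 ± 2631 FPKM, OLEO3 rose from 0.84 ± 0.829 to 3126 ± 896, and HSD5 stood at 126 ± 9.28. The late embryogenesis genes ECP63, M10, XERO1 and TIP3;2 stood at 73.8 ± 5, 71.8 ± 6.88, 90 ± 16.9 and 588 ± 89.2 FPKM against none in WT. Of the measured members, 12 of 14 seed regulators, 12 of 12 storage, 12 of 12 oil and 20 of 20 late embryogenesis genes were called higher (as many when adjusted over the list alone), and 2 regulators were called lower. The camera adjusted p were 1.68e-26, 3.22e-161, 1.11e-44 and 2.63e-64, all held with an estimated correlation. Replicate 3 was nearer to WT in these groups, a median 0.293 to 0.492 of the way from the mean of the other 2 replicates.

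**Figure D2:**
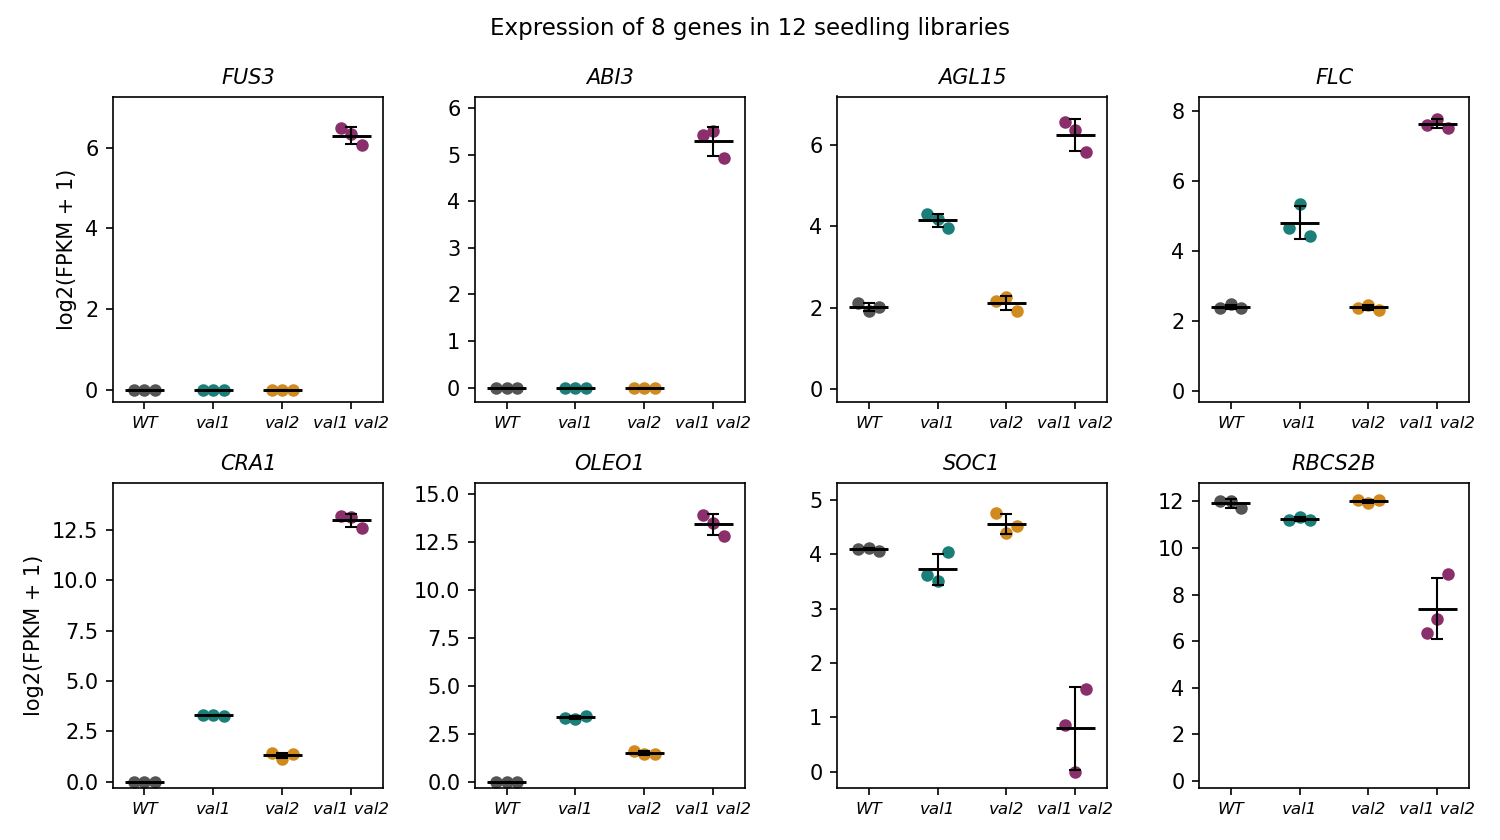
Expression of 8 genes as log2(FPKM + 1) in each library (points, 3 per genotype), with the group mean (bar) and SD (error bars). FUS3 and ABI3 lie at 0 outside the double mutant, FLC and AGL15 are raised in val1 and further in val1 val2, and SOC1 and RBCS2B are lowest in val1 val2.

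Photosynthesis genes fell in the double mutant. RBCS2B, a small subunit of Rubisco, fell from 3868 ± 482 to 223 ± 212 FPKM (log2 change -4.52, SE 0.484, limma adjusted p = 1.85e-05). The photosystem I subunits PSAN and PSAK fell from 845 ± 244 to 167 ± 61.4 (1.72e-05) and from 1364 ± 34.9 to 413 ± 156 (4.1e-05). Of 28 measured members 25 were lower and 1 higher (25 and 2 over the list alone; camera adjusted p = 0.00026, but adjusted p = 0.454 with an estimated correlation). Replicate 3 stood a median 0.284 of the way to WT. The largest falls of all included NdhL, a subunit of the chloroplast NDH complex, from 126 ± 6.53 FPKM to no locus (1.83e-09), and FBA5, a fructose-bisphosphate aldolase, from 102 ± 6.77 to 1.15 ± 0.979 (-5.67, 2.51e-08). RbcX1, a Rubisco assembly factor, fell from 82.8 ± 18.2 (n = 2) to 2.74 ± 4.75 (0.000565), and BT1, a BTB scaffold protein, from 181 ± 23.5 to 8.34 ± 7.68 (-4.57, 4.52e-06). AT2G04039 and AT3G06950 went from 27.6 and 24.9 FPKM to no locus, AT4G13500 from 122 to 6.15 (n = 2) and AT3G46490 from 37.2 to 0.915. SDH3-2 went from 70.9 ± 2.31 (n = 2) to no locus (0.00904), a call lost with missing loci entered as 0 (0.136). Root tissue markers fell too, 11 of 14 lower and 1 higher (as many over the list alone; camera adjusted p = 0.0051, but adjusted p = 0.397 with an estimated correlation). The root iron transporter IRT1 stood at 25.2 ± 4.11 FPKM in WT and had no locus in val1 val2 (8.78e-07), and the tonoplast aquaporin TIP2;3 fell from 42.2 ± 5.96 to 2.39 ± 0.976 (9.45e-08).

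Flowering genes split. FLC rose from 4.31 ± 0.246 to 200 ± 18.9 FPKM in val1 val2 (log2 change 5.24, SE 0.191, limma adjusted p = 4.25e-09) and MAF5 from 10.2 ± 0.476 to 33.9 ± 3.44 (6.83e-07). SOC1, which promotes flowering, fell from 16.2 ± 0.306 to 0.9 ± 0.948 (-3.31, 6.99e-06), SVP from 44.1 ± 9.18 to 5.86 ± 2.83 (7.54e-06), and FT went from 3.18 ± 1.53 to no locus (0.000473). Of 21 flowering time genes 3 were higher and 11 lower (as many over the list alone; camera adjusted p = 0.443). Of 7 floral genes 2 were higher and 2 lower (as many over the list alone; 0.443). AT5G15800 (SEP1) and AT3G02310 (SEP2) stood at 1.74 ± 0.255 and 5.22 ± 3.27 against none in WT. SEP4 went from 7.29 ± 0.32 to no locus and AGL24 fell from 15.7 ± 7.21 to 3.35 ± 1.58. AG had no locus in any library, and SEP3 stood at 6.34 ± 0.616 in WT and 5.90 ± 2.78 in val1 val2 (0.644). Meristem genes rose, 8 of 10 with 1 lower (as many over the list alone; camera adjusted p = 0.00819, but adjusted p = 0.104 with an estimated correlation). CUC1, which sets organ boundaries, rose from 0.63 ± 0.577 to 16.2 ± 4.91, WOX5, a gene of the root stem cell niche, from 1.03 ± 0.113 to 22.1 ± 9.76, and STM, which maintains the shoot meristem, from 4.46 ± 0.309 to 19.1 ± 6.95, and the stem cell peptide gene CLV3 stood at 4.88 ± 2.88 against none. Of 20 Polycomb and partner genes 6 were higher and 8 lower (as many over the list alone; camera adjusted p = 0.396; median -0.059 and mean 0.215). BMI1A rose to 30.1 ± 3.35 (2.39e-07), BMI1B to 17.44 ± 3.5 and RING1B from 6.92 ± 0.782 to 16.6 ± 0.0945. VIN3, which represses FLC after cold, stood at 7.34 ± 0.917 against none.

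Hormone and defence genes changed in the double mutant as well. Gibberellin metabolism rose as a list, 6 of 9 higher and 1 lower (6 and 2 over the list alone; camera adjusted p = 0.00591, 0.00876 with an estimated correlation). GA20OX3 stood at 115 ± 31.7 FPKM and GA1 at 5.14 ± 1.88 against none in WT, while GA3OX1 went from 4.72 ± 1.48 to no locus (limma adjusted p = 6.36e-07). Abscisic acid genes were higher in 7 of 12 and lower in 1 (as many over the list alone; camera adjusted p = 0.0154, but adjusted p = 0.186 with an estimated correlation and 0.0755 without val1 val2 replicate 3). ABA2, an enzyme of abscisic acid synthesis, rose from 10.6 ± 1 to 46.9 ± 9.33 and CYP707A2, which degrades it, from 0.921 ± 0.326 to 20.7 ± 3.44. Of 13 auxin genes 7 were higher and 3 lower (as many over the list alone; 0.396), YUC4 standing at 11.8 ± 4.08 against none and PIN7 falling from 56.6 ± 3.81 to 21.1 ± 4.26. Stress and defence genes rose, 8 of 11 (10 over the list alone; camera adjusted p = 1.25e-09, held with an estimated correlation). The pathogenesis-related genes PR1 and PR2 stood at 360 ± 114 and 55.2 ± 9.49 and the senescence gene SAG13 at 64.7 ± 31.9 FPKM against none. Of 14 cell division genes 8 were higher (as many over the list alone; 0.146), for example CDKB1;1 from 3.41 ± 0.682 to 9.13 ± 0.556. Of 9 reference genes 1 was higher and 3 lower (as many over the list alone; 0.831). ACT2 fell from 652 ± 36.2 to 154 ± 95.7 and GAPC2 rose from 762 ± 33.7 to 1808 ± 466. The calls of ACT8 and PP2AA3 were lost under median-ratio scaling (0.0516 and 0.0543), that of ACT8 also without val1 val2 replicate 1 (0.0721) and that of PP2AA3 without WT replicate 3 (0.0575) or val1 val2 replicate 2 (0.0529).

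Altogether 10435 of 17654 genes (59.1%) were called in val1 val2 against WT, 4342 higher and 6093 lower, 5563 of them by at least 2-fold, and in 11383 genes (64.5%, chance 10%) the groups did not overlap. Without replicate 3 of the double mutant the count was 11107. The median log2 change of all genes was -0.144 as deposited, 0.037 under median-ratio scaling and -0.326 as TPM, so the split of directions rests on the scaling. The calls were 5479 higher and 4923 lower (52.7% higher) under median-ratio scaling and 3544 and 7579 (31.9%) as TPM, against 41.6% as deposited.

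**Figure D3:**
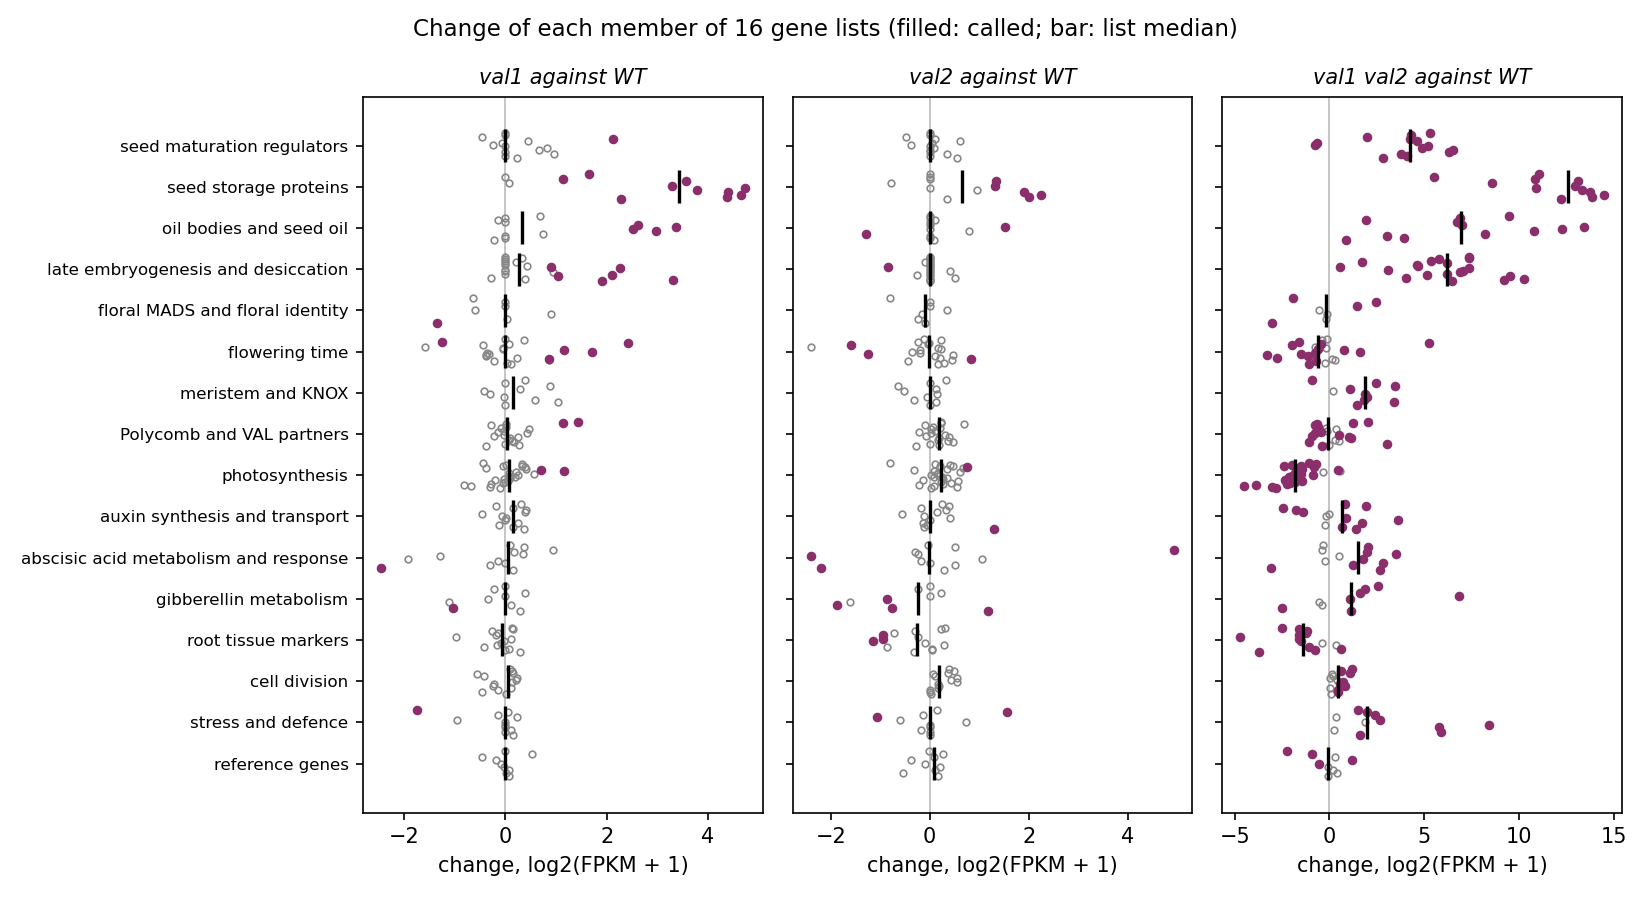
Log2 change on the FPKM + 1 scale of each measured member of 16 gene lists in the 3 mutants against WT, with called genes filled and the list median as a bar. Storage protein genes have medians of 3.43 in val1, 0.66 in val2 and 12.6 in val1 val2, and the horizontal scales differ between panels.

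The double mutant was also set against each single mutant, to ask what the second mutation adds. Against val1, the storage genes CRA1 and SESA3 went from 8.82 ± 0.203 and 24.2 ± 0.921 FPKM to 8190 ± 1696 and 24650 (n = 2), and FLC from 28.3 ± 9.9 to 200 ± 18.9. In both comparisons 12 of 14 seed regulators were higher and 2 lower (as many over the list alone), and all 12 storage and all 12 oil genes were higher (camera adjusted p of 1.78e-34 or smaller), with 25 or 26 of 28 photosynthesis genes lower. The photosynthesis lists passed camera at 1.22e-05 against val1 and 4.16e-05 against val2 but not with an estimated correlation (adjusted p = 0.347 and 0.497). In total 10300 genes were called against val1 (4522 higher, 5778 lower) and 10581 against val2 (4418 and 6163).

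To test whether the double mutant departs from the sum of its single mutants, the interaction was fitted. Its largest positive values were seed genes with no locus in WT, val1 or val2 except TIP3;1, which stood at 0.426 ± 0.738 FPKM in val1. They were the lipid transfer protein genes AT5G38160 and AT5G38170 at 3226 ± 1588 and 1070 ± 529 FPKM in the double mutant, AT4G33145 at 2493 ± 1620, the defensin LCR67 at 970 ± 261 and the seed aquaporin TIP3;1 at 1300 ± 439 (limma adjusted p = 1.61e-09 to 2.1e-07). Among the most negative, ASN1, an asparagine synthetase, stood at 70.9 ± 41.3 FPKM in WT, 316 ± 29.2 in val1, 204 ± 48.4 in val2 and 8.66 ± 5.77 in val1 val2 (log2 interaction -6.85, SE 0.639, 1.38e-05). The thionin gene AT1G66100 stood at 5.79 ± 1.39, 8.06 ± 2.38, 34.6 ± 4.61 and none (2.16e-07). WRI4, a regulator of wax synthesis, stood at 30.1 ± 10.8, 49.1 ± 2.33, 48.8 ± 6.73 and 1.14 ± 1.98 (8.29e-05), and NdhL and AT4G13500 completed the 5. FLC departed by 2.83 (SE 0.27, 1.62e-05) and AGL15 by 1.998 (SE 0.26, 0.000141), whereas VAL3, SEP3 and FT gave adjusted p = 0.452, 0.943 and 0.938. Over all genes 8254 of 17654 were called, 3764 above and 4490 below the sum. Storage (12 of 12 above), seed regulators (12 above, 1 below), oil (11 above, 12 over the list alone), late embryogenesis (19 above, 20 over the list alone), gibberellin (7 above, 1 below) and stress and defence (8 above) passed camera (adjusted p = 7.08e-05 or smaller) and held with an estimated correlation. Photosynthesis (25 below, 3.69e-06), meristem (8 above, 1 below, 0.0277) and abscisic acid (8 above and 1 below, 9 and 1 over the list alone, 0.0153) did not hold (adjusted p = 0.457, 0.18 and 0.18 with an estimated correlation), and the last 2 were also lost without val1 val2 replicate 3 (0.103 and 0.0763). The 7 other lists gave 0.0563 to 0.981.

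Calls of the single mutants were then compared with each other and with those of the double mutant. Between val1 and val2, 80 genes were higher in both and 74 lower in both, against 6.8 and 8 for independent lists, and 13 were opposite (15.5). Between val1 and val1 val2, 258 were higher in both (94.7 for independent lists), 170 lower in both (103.9) and 105 opposite (206.9), with FLC, MAF5, AGL15 and BMI1A among the shared rises. The storage genes are counted there too, and carry-over from the val1 val2 libraries, which was not excluded for most of them, would itself give such sharing. Between val2 and val1 val2, 129 were higher in both (76.2), 170 lower in both (162.2) and 261 opposite (222.6), with COR15A higher in val2 and at 0.390 FPKM in the double mutant (not called, limma adjusted p = 0.49). All 3 comparisons use the same WT libraries. The fold changes correlated at 0.427, 0.308 and 0.075 (Pearson, across genes, which are not independent) against 0.503 to 0.506 in simulations without effects. The covariances were 0.0933, 0.211 and 0.0508 against 0.0333, 0.0334 and 0.0335 simulated, differences of 0.06, 0.178 and 0.0173. The 3 WT libraries are too few to split, and how many shared calls come from them was not tested, so part of the excess over independent lists may come from the shared controls. The overlaps moved with single libraries: 154 between val1 and val2 became 389 without val1 val2 replicate 3, 82 and 81 without WT replicate 1 and 2, 97 and 93 without val1 replicate 2 and 3, and 69 and 93 without val2 replicate 1 and 3. That of 428 between val1 and val1 val2 became 724 without val1 val2 replicate 3, and that of 299 between val2 and val1 val2 became 697 without the same library, 168 and 133 without WT replicate 1 and 2, and 107, 186 and 157 without val2 replicates 1, 2 and 3.

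Finally, the val1 change was compared in plants with and without VAL2, using val1 against WT and val1 val2 against val2, which share no library. Of the 385 genes higher in val1, 271 were also higher in val1 val2 than in val2 and 235 of these were called there, while of the 301 lower genes 167 were lower and 121 called. Among all 17654 genes, 4418 were called higher and 6163 lower in val1 val2 against val2. Only the higher genes stood well above that share, and the lower genes were near it. Over all genes the changes correlated at 0.168 (Spearman 0.066), across genes, which are not independent replicates. Over the genes called in val1, the storage genes included, they correlated at 0.509. A simulation without effects gave -0.001, an outcome fixed in advance because no library is shared, so it adds no support. Carry-over from the val1 val2 libraries into val1, not excluded for most storage genes, could itself raise both correlations. The spread of the changes was 0.471 (SD, log2) with VAL2 and 1.495 without. The val2 change with VAL1 (val2 against WT) and without (val1 val2 against val1) correlated at -0.066.

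**Figure D4:**
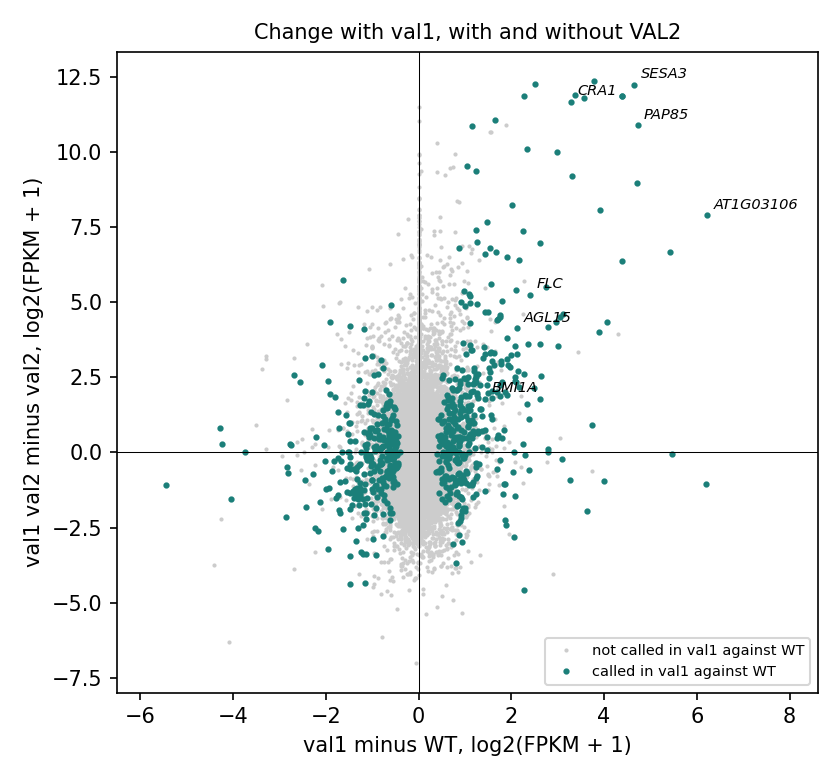
Each point is a gene, with its log2 change in val1 against WT on the horizontal axis and in val1 val2 against val2 on the vertical axis, and genes called in val1 against WT are coloured. Named genes such as FLC and CRA1 lie at the upper right, and the correlation over all genes is 0.168.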

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

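The carry-over and scaling tests in this part were chosen after the results were seen, and the admixture, clock, touch and split tests were written before their own values were computed. The val1 change differed between plants with and without VAL2 in 8254 genes, found by the test of the interaction: FLC, for example, rose from 4.31 to 28.3 FPKM in the presence of VAL2 and from 4.27 to 200 in its absence. Of 100 splits of the libraries only the real one, 1 split, gave as many calls, while the highest other gave 6202 and the median other 0. These splits mix libraries of all 4 genotypes, including the double mutant that stands apart. They exclude only a grouping without any genotype difference, and cannot tell a departure from the sum from additive changes. For each of the 5 comparisons of 2 groups only 10 splits exist, too few for a share under 0.05: the real split gave 686, 780, 10435, 10300 and 10581 calls, the highest other 5, 6, 7, 3 and 7, and in each 1 split, the real one, gave as many.

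Loci outside protein-coding genes held 6.01% of the FPKM in the val1 val2 libraries (SD 2.91, n = 3; 9.29, 5.01 and 3.74%), against 0.783 ± 0.047% in WT, 1.32 ± 0.157% in val1 and 1 ± 0.3% in val2, a signal in loci that the comparisons did not use. The 7 loci that were among the 5 most abundant of such loci in any val1 val2 library held 8.24, 3.78 and 2.71%, and without them 1.1 ± 0.107% was left, against 0.74 ± 0.075% in WT, 1.18 ± 0.159% in val1 and 0.883 ± 0.202% in val2. Most of the excess over the single mutants thus lay in these 7, which were picked for their abundance in val1 val2. The most abundant was on chromosome 5 at 18891009 to 18891182, over the long noncoding RNA AT5G06845, with 55069, 22066 and 18407 FPKM in the double mutant. No locus outside protein-coding genes was listed there in the other libraries. Loci that also overlap a protein-coding gene were not searched, so signal there in the other libraries was not excluded. These 7 loci are 161 to 208 bases long, near the fragment length, so their FPKM can be inflated, and no biological explanation was tested.

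The low levels of storage and oil body genes in the single mutants may come from the gene's own transcription or from carry-over of RNA or reads from the val1 val2 libraries. In val1, of 6 genes for which carry-over at the median share of 0.113% predicts at least 20 fragments, 0 lacked a locus, which own transcription allows as well, while AT5G38160, AT4G33145 and AT5G38170 (3226, 2493 and 1070 FPKM in val1 val2) had none at about 8.5, 6.6 and 2.6 expected fragments. The expected fragments are a rough scale: SESA2, SESA3 and SESA4 had a locus in every val1 library at only 1.8. Neither these loci nor the missing ones can therefore decide. Over all 13 storage and oil body genes with a locus in every val1 library the share spanned 0.0773 to 0.987% (10th to 90th percentile, 12.8-fold), with PAP85 at 1.2% and HSD5 at 4.11%, but the other 11, picked for lying within 5 times of the median, spanned 0.0762 to 0.133%, so carry-over stays open for them. It would have to have passed over WT: CRA1 and AT4G28520 had no locus there, while this share predicts about 300 and 201 fragments for them in val1. Carry-over at this 1 share would not give the levels of 59 genes over 5 times above it (median 20%), PAP85, HSD5 and TIP3;2 at 1.55% among them. These genes were picked by that ratio and for a locus in every val1 library. Carry-over was therefore not excluded gene by gene, least for those near the limit, such as RNS1 at 0.659%. In val2 the 6 storage and oil body genes with a locus in every library spanned 0.0158 to 0.0201% (10th to 90th percentile, 1.27-fold). Of only 2 genes with 20 expected fragments 0 lacked a locus, which cannot tell, and 18 genes lay over 5 times above the share of 0.0182%. AT1G03880, PAP85 and OLEO2 had no locus in val2 at 12.6, 6.1 and 4 expected fragments, while SESA2, SESA3 and SESA4 had one in every val2 library at 0.3.

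Replicate 3 of val1 val2 was nearer to WT than the other 2, which could reflect admixture of seedlings with WT levels, scaling, or weaker changes in those plants. A mixture predicts the same share of WT from all genes. The share was 0.362 from 1214 genes that rose and 0.178 from 611 that fell, a difference of 0.184, over the limit of 0.1 set for it. This cannot exclude a mixture, because the other 2 replicates were taken as unmixed though they differ themselves (rank correlation with the WT mean 0.682 and 0.727). The quartiles of the shares also overlap (0.128 to 0.52 and 0.101 to 0.251). This is the only double mutant library with an unbroken VAL1 locus, at 24.3 FPKM, so admixture of WT seedlings or of other plants with an intact VAL1 stays open. A scaling cause was excluded, because the rank correlation with the WT mean, which scaling does not change, was still higher by 0.077 than in the nearer of the other replicates. Differences between plants in the strength of the change stayed open and were not tested.

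Genes lower in val2 may reflect handling as well as genotype. Of 10 clock genes 1 was called (2 over the list alone), PRR7, which fell from 8.68 ± 1.25 to 3.78 ± 0.344 FPKM (limma adjusted p = 0.0263), fewer than the 4 that a different hour of harvest was set to predict. The clock list gave camera adjusted p = 0.122 but adjusted p = 0.0464 with an estimated correlation. GI, a clock gene seen first and kept off the list, stood at 40.9, 5.23 and 4.16 FPKM in WT and 1.11 in val2 (limma adjusted p = 0.0506). Without WT replicate 1 GI was called (0.00105), with a log2 change of -1.43 against -2.39 with all libraries. In val1 the clock list gave camera adjusted p = 0.13, and 0.0414 with an estimated correlation (3 lower over the list alone). In val1 val2, where 59.1% of all genes were called, 2 of 10 clock genes were higher and 6 lower (as many over the list alone). The list gave camera adjusted p = 0.178 there, and 0.149 with an estimated correlation. ELF3 fell from 28.6 to 14.4 FPKM and LUX from 43.1 to 24.35. The 2 higher, LHY and RVE8, are named after their values were seen. The hour of harvest thus stays open for each mutant. Rapid touch and wound genes were lower in val2 as a list (camera adjusted p = 7.85e-13, and adjusted p = 0.0464 with an estimated correlation), with 6 of 19 called and 12 over the list alone, among them TCH2 (35.6 to 10.8 FPKM) and MYB44 (93.7 to 32.2), so that handling and genotype could not be told apart. They were lower in val1 as well (camera adjusted p = 0.00437, but adjusted p = 0.38 with an estimated correlation; median -0.61) and mostly higher in val1 val2 (12 of 19 called higher, median 1.22, camera adjusted p = 0.118), where replicate 3 was the highest of its group in 19 of 19 genes, as WT replicate 2 was in 17, so single libraries stand apart in both groups.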

How the results depend on the processing

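Of 11535 values of named genes and lists, 11170 kept their side of the threshold, 247 were no longer called and 118 newly called. No call reversed, but some values that were not called, or list medians, changed sign. The cause of the changes below was not tested, except that a cutoff of 2-fold keeps fewer genes. Weights per library gave 1877 calls in val1, 2310 in val2, overlaps of 632, 1001 and 904, and VAL1 in val1 at -1.16. The 2-fold cutoff gave 345 in val1, 371 in val2 and 5563 in val1 val2, and only the compared groups gave 1297 calls and 1 list in val2. Lists called numbered 7 in val1 with the block, 2 in val2 with a pseudocount of 0.1, 2 with an estimated correlation and 1 with fry, and 6 in val1 val2 with an estimated correlation. In val1 val2 fry called 15 lists, among them auxin, cell division, Polycomb, floral and flowering time, which camera did not call. The correlation of the val1 change was 0.19 with a pseudocount of 0.1 and 0.145 with loci over several genes kept. VAL2 was at -0.56 in val2 and -0.42 in val1 val2 both with the largest locus and with such loci kept; these rules were chosen after seeing the data. Leaving out single libraries gave 389 to 1280 calls in val1, 310 to 1619 in val2, 9358 to 11107 in val1 val2, 9192 to 11019 and 9535 to 11282 against val1 and val2 and 7355 to 9519 for the interaction; overlaps of 69 to 389, 287 to 724 and 107 to 697; correlations of 0.126 to 0.184; 3 to 7, 3 to 4, 9 to 10 and 7 to 10 lists; VAL1 at -1.51 to -0.92 in val1 and -0.41 to 0.07 in val1 val2; and VAL2 at -0.996 to -0.84 in val2 and -0.72 to -0.57 in val1 val2. The replicate numbers did not pair the libraries: residuals of the 18 pairs with the same number correlated at -0.036 to 0.071, other pairs at -0.085 to 0.092, and 6 of 12 libraries correlated best with their own number. With the number as a block, the counts were 597, 596, 10288, 10174, 10476 and 8108. With a median of 209 to 322 fragments per locus, low genes were measured with few fragments. The simulation recovered 62 of 100 2-fold changes, but it changed no low gene, so recovery of low genes is not known.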

Other observations

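The tests in this part were written before their values were computed, for patterns seen first in the results. After 3 IRON MAN peptide genes were seen to fall in val1, a list of iron deficiency genes without them was tested. It was lower in val1 (camera adjusted p = 6.16e-10, and adjusted p = 0.000628 with an estimated correlation), with 6 of 12 genes called and 9 over the list alone. The bHLH regulators of iron uptake BHLH100 went from 4.70 FPKM to no locus (limma adjusted p = 0.000515), BHLH39 and BHLH101 fell from 7.73 to 1.65 (0.0164) and from 3.69 to 0.596 (0.0174), and the phloem transporter OPT3 from 77.2 to 34.0 (0.000287). A lower iron deficiency response in val1 fits these values, though a difference between plates could give the same. In val1 val2 8 of 12 genes were lower and 2 higher (as many over the list alone), with a larger median fall of -1.65 against -0.98 in val1, though camera did not pass (0.0858), and in val2 1 was lower (0.122). The peptide genes seen first did not follow there: AT1G47400 and AT1G47395 stood at 32.3 and 26.4 FPKM in val1 val2 (limma adjusted p = 0.116 and 0.497), and only AT2G30766 fell, to 3.44 (0.000337).

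Genes called close to the mutated loci might come from linked sequence. Within 1000000 bases of VAL1, 14 of 338 genes were called in val1, a share 1.07 times that elsewhere (Fisher exact p = 0.776), and near VAL2 21 of 382 in val2, 1.25 times (0.311), so calls were not concentrated there. The 338 and 382 genes could hold only a minority of the 686 and 780 calls in any case. The test therefore cannot settle where most calls come from, and linked sequence farther away was not tested.

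AT1G75945 had 0 FPKM in the 3 WT libraries and 43.2, 41.3 and 41.7 in val1, val2 and val1 val2, and AT3G29633 had 13.6 in WT and no locus in any mutant. AT5G20790 stood at 32.9 FPKM in WT, 4.84 in val2 and 286 in val1 val2.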
